A study of Glycine max with 8 samples.

How the data were processed

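Total RNA from whole soybean seeds was measured on 8 arrays of 1-colour Agilent design, 2 of dry seed, 3 of seed imbibed for 8 h and 3 of seed imbibed for 16 h. Per the labels' protocols, about 30 dry seeds were soaked in 1% hypochlorous acid, washed and kept on wet cotton in the dark at 25 °C, and 3 RNA samples per stage were extracted with a silica column kit. Per the labels' protocols, 200 ng of total RNA was amplified linearly and labelled with a cyanine dye. Groups and replicate numbers were taken from the sample titles. The array layout put 4 arrays on each of 2 slides, and each slide held all 3 stages. The third dry sample was not analysed here.

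The deposited scanner files give each spot's brightness as intensity on a linear scale. Per the file headers, the arrays were extracted with Agilent Feature Extraction 10.7.3.1, whose processed signal is an intensity after background subtraction and detrending within the array, with no normalization between arrays. Median signal and local background intensity of each spot, per the file headers, were used only in an alternative. The series' deposited value table holds log2 values. Set against the scanner files, each of its columns equals log2 of the processed signal minus that array's 75th percentile, up to a constant between -0.0027 and -0.00084, so its scale and centring are known from the data, and there is no ratio whose direction could be in doubt. Its column medians lie between -3.10 and -2.52 log2. It has 42808 entries, of which 60 have no soybean probe in the scanner files as used here, and it served as an alternative.

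Main values were log2 of the processed signal minus each array's 75th percentile over 42748 soybean probes. The 1417 control spots were left out, as were 0 to 4 outlier spots per array, and no spot was saturated. A probe was tested where it was well above background on every array of at least 1 stage, which kept 28792 probes. One linear model with a mean per stage was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, 5 residual degrees of freedom), with 2-sided tests of 8 h against 0 h, 16 h against 0 h and 16 h against 8 h. A call is a Benjamini-Hochberg adjusted p under 0.05 over the tested probes. Dim probes carry a bound, given as "at least N-fold": the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. Values per array were compared with exact permutation tests in scipy 1.17.1 under Python 3.11.15. The spike-in mean is the mean log2 signal of 7 of the 10 E1A control probes, each with 32 spots, that were above background and below saturation on all arrays. The position of an array between dry seed and 16 h is its projection on the line between the 2 group means, with the array itself left out of its own group's mean. Sizes of change are summarised over called probes that were well above background on every array of both stages compared, a restriction chosen after seeing the data, since a fold against an undetected level is no measurement. Intensity over background takes the place of depth on these arrays, and 18483 probes were well above background on all 8 of them.

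The probes carry only sequence accessions and clone names. None of the 42748 matched the 59048 genes of the reference table used here (0 matched), so no gene is named. For the same reason the tests of 37 gene lists that had been planned, among them markers of seed coat and of embryonic axis and root, were not run, and neither were the alternatives with 1 probe per gene. The rule for named features, written before the data were examined, took called features with a product name that were measured on every array of both groups with no overlap between the groups, in order of the size of the change. Without product names it was applied to probes, for 16 h against dry seed, and held to the 2 largest rises and the 2 largest falls.

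The limma step was tested on simulated data with the spread of the real arrays, on 28785 probes of which 200 were changed. For 16 h against 0 h it recovered 0% of 1.5-fold, 12% of 2-fold, 82% of 4-fold and 94% of 8-fold changes, with 0 false calls among 28585 unchanged probes. For 8 h against 0 h it recovered 6% of 2-fold and 86% of 4-fold changes with 6 false calls, and for 16 h against 8 h it recovered 30% and 94% with 9. In the real data 64.6% of tested probes were called for 16 h against 0 h and 60.3% for 16 h against 8 h. Benjamini-Hochberg adjustment is less strict where more probes change. The simulated shares therefore do not give the recovery in these 2 comparisons.

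Alternatives set before the data were examined were normexp background (offset 50), quantile normalization, median centring, the percentile over detected probes, spike-in centring, no filter and a stricter filter on dim probes, slide as a block and within each slide, the replicate number as a block, only the 2 groups compared, each array left out in turn, eBayes with trend, a 2-fold minimum and the deposited log2 values. Normexp used the median spot signal in place of the mean signal, which was not used here. A common floor on dim values, and normexp without spots below their local background, were added after seeing the data.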

Results

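Whole soybean seeds (Glycine max, cultivar Suzumaru) were profiled dry and after 8 h and 16 h of imbibition, the uptake of water with which germination begins. The series is concerned with early imbibed soybean as a protein food, and its design sets the 3 imbibition times against each other. Dry seed had 2 arrays and each imbibed stage had 3. Per the labels, the 8 h sample held seeds that had taken up over 0.06 g of water, and the 16 h sample held seeds that had germinated or had taken up over 0.33 g, so time and selection on water uptake go together. About 20 to 25 seeds of a stage were divided into 3 portions and milled separately. The p-values therefore measure the spread among portions of 1 lot of seeds per stage, which may be technical. Each array measured 42748 soybean probes in 1 colour, and the number of arrays limits the precision. The files pair the probes with clone and sequence identifiers and not with gene names, so the results are given for classes of probes and for 4 single probes.

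More of the soybean array was detected after 16 h of imbibition than in dry seed. Dry seed had 21759.5 ± 2266 probes well above background (SD, n = 2), 8 h seed 23916 ± 3845 (n = 3) and 16 h seed 30581 ± 1012 (n = 3). Every 16 h array exceeded every dry and every 8 h array. The 16 h arrays also stood higher against the viral E1A transcripts (spike-in RNA of known sequence on Agilent arrays). The 75th percentile of the soybean probes lay at -5.52 ± 0.017 log2 from the spike-in mean in dry seed, at -5.49 ± 0.28 at 8 h and at -4.07 ± 0.28 at 16 h. That is 2.73-fold higher at 16 h than in dry seed and 2.68-fold higher than at 8 h. The spike-in mean itself was 13.24 ± 0.032, 13.43 ± 0.050 and 13.32 ± 0.18 log2 in dry, 8 h and 16 h seed. In a two-sided exact permutation test both measures gave p = 0.2 for 16 h against dry seed and p = 0.1 for 16 h against 8 h, the smallest values these group sizes allow. After Benjamini-Hochberg adjustment over 18 such tests the exact p became 0.257 in each case. The 8 h and dry arrays overlapped in both measures (exact permutation p = 0.6 and 1). Within slide 1 the detected probes numbered 20157 in dry seed, 25355 at 8 h, and 31193 and 31137 at 16 h. Within slide 2 they numbered 23362 in dry seed, 26835 and 19559 at 8 h, and 29413 at 16 h. Relative to the spike-ins, the 16 h arrays of slide 1 lay at -4.15 and -3.75 against -5.51 for its dry array, and the 16 h array of slide 2 lay at -4.30 against -5.53.

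**Figure D1:**
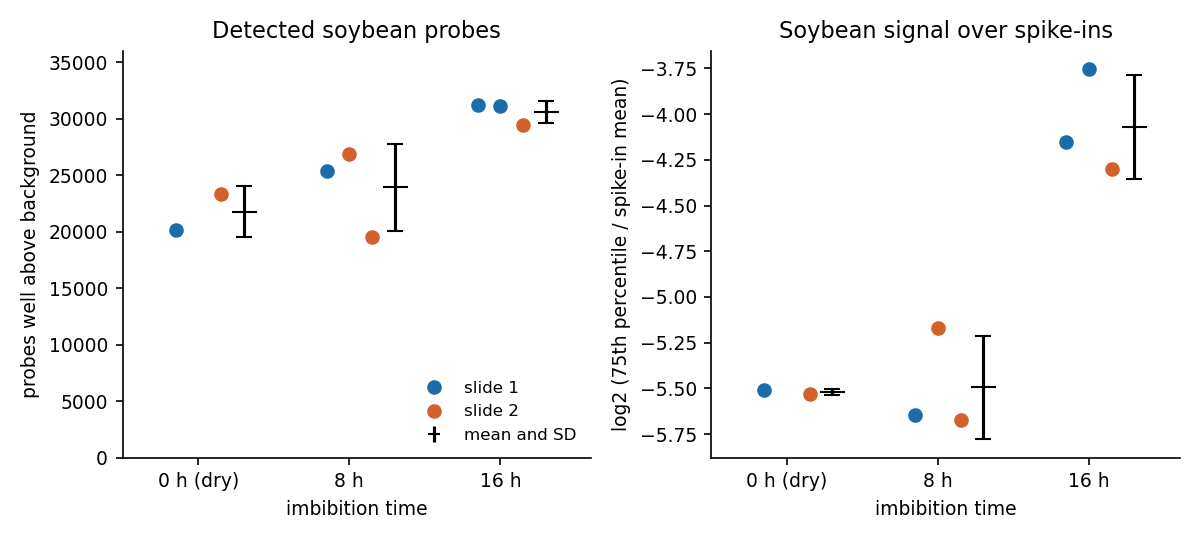
The left panel plots the number of soybean probes well above background on each array, and the right panel the log2 ratio of the array's 75th percentile to its spike-in mean, both against imbibition time. Each point is 1 array coloured by slide, bars are mean ± SD, and the 3 arrays at 16 h lie above all others in both panels.

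Seed imbibed for 16 h differed from dry seed at many of the probes tested. Of 28792 probes tested, 8881 were higher and 9722 lower at 16 h (limma, Benjamini-Hochberg adjusted p under 0.05, levels relative to each array's 75th percentile). With normexp background limma called 2115 higher and 3991 lower, and 5408 and 14948 once spots below their local background were left out. Of the 8881 and 9722, 3891 of the higher probes and 9190 of the lower ones were well above background on every array of both stages. Over those the median change was 2.13-fold among the higher probes and 2.26-fold among the lower ones, with 205 at least 8-fold higher and 357 at least 8-fold lower. The groups did not overlap in 80.8% of tested probes, where arrays in random order would give 20%. The filter chose probes by their detection within a stage, which can favour separation, so 20% is not the share to expect after it. The probe with the largest rise among those measured in both stages, CD417265.1_364, went from -0.50 ± 0.36 log2 (SD, n = 2) in dry seed to 8.04 ± 0.17 (n = 3) at 16 h. This is a rise of 8.53 ± 0.48 (SE), or 369.9-fold, with a limma adjusted p of 0.000121. The next, BU546969.1_505, rose by 6.39 ± 0.58 (SE), or 83.8-fold, with a limma adjusted p of 0.000176. The largest falls were those of GMFL01-30-B13-R_365, at -5.73 ± 0.86 (SE) log2, and BE823736.1_624, at -4.89 ± 0.50. Their limma adjusted p values were 0.000995 and 0.000247, and they were 53.2-fold and 29.7-fold lower. GMFL01-30-B13-R_365 moved with single arrays left out, to -5.06 log2 without 16 h replicate 1 and to -6.38 without 16 h replicate 2. Over 25 alternative settings the 2 rises ranged from 8.09 to 9.98 log2 for CD417265.1_364 and from 4.87 to 7.84 for BU546969.1_505. The 2 falls ranged from -6.38 to -4.28 for GMFL01-30-B13-R_365 and from -5.42 to -3.44 for BE823736.1_624. Quantile normalization put CD417265.1_364 at 9.63, normexp background put BU546969.1_505 at 4.87 and GMFL01-30-B13-R_365 at -4.49, and slide 2 alone put BU546969.1_505 at 5.67. All 4 probes were well above background on all 8 arrays. Detection on every dry and 16 h array, and no overlap between these groups, were conditions of their choice.

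**Figure D2:**
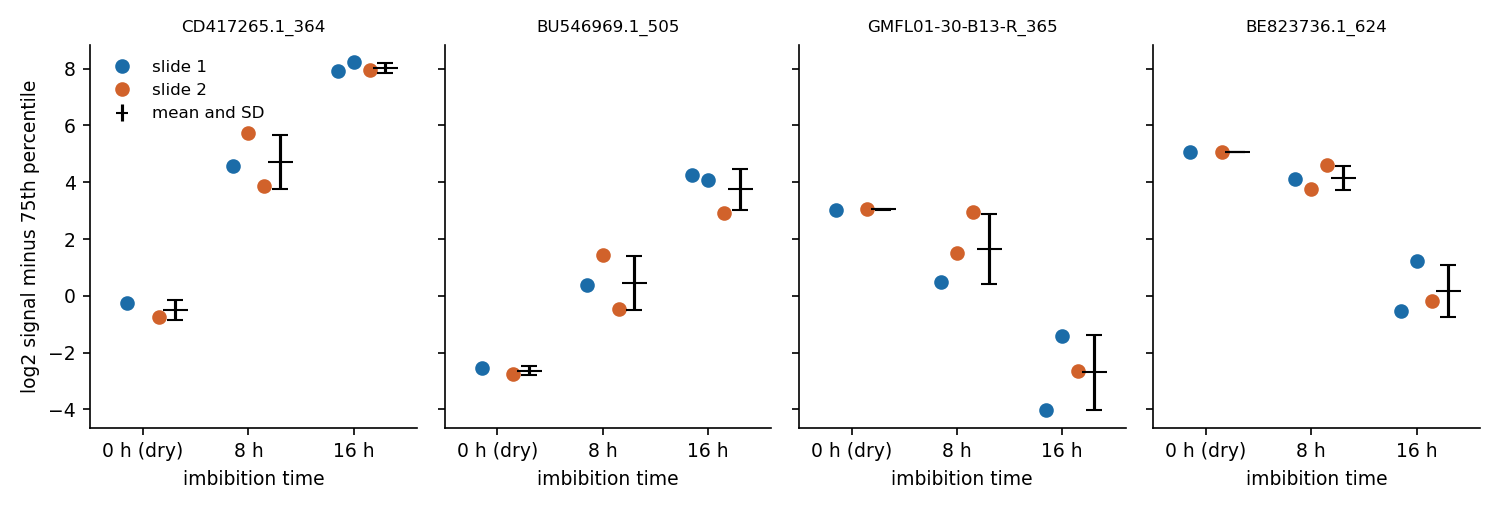
The log2 signal of the 4 named probes relative to each array's 75th percentile is plotted against imbibition time, with 1 panel per probe, 1 point per array coloured by slide, and bars for mean ± SD. CD417265.1_364 climbs from -0.50 to 8.04 and BE823736.1_624 drops from 5.07 to 0.17 between dry seed and 16 h.

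Transcripts not well above background in dry seed and well above it after 16 h made up a large class. A total of 5760 probes were well above background on all 3 arrays at 16 h and on neither dry array, against 22 in the opposite direction. Of the 5760, limma called 3693 higher at 16 h. A bound above 1-fold could be given for 3095 of the 5760, with a median of at least 2.08-fold over these 3095, and 314 called probes were at least 8-fold higher, the largest by at least 378-fold. All 22 of the opposite class were called lower, the largest by at least 28.4-fold. Dry seed replicate 1, with a median of 7.10 intensity units on the negative controls against 3.55 in replicate 2, had the higher floor of the dry arrays. The lowest soybean signal well above background lay at -2.91 and -3.78 log2 from the 75th percentile on the dry arrays, and at -5.42, -5.49 and -4.92 on the 16 h arrays, so dimmer probes could pass at 16 h. The floors of the 8 h arrays were -3.97, -4.32 and -2.81.

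The balance of rises and falls at 16 h depended on the filter on dim probes and on the scaling of the arrays. The filter admits probes detected at 1 stage only, and far more of these were detected at 16 h than in dry seed. Without it, 8173 probes were called higher and 15490 lower than in dry seed (limma). Of these 15490, 5685 were among the 9128 probes well above background on no array, where the median change was -1.74 log2 relative to the 75th percentile and -0.29 relative to the spike-ins, so they are not falls of measured transcripts. Over the 18483 probes well above background on all 8 arrays 4029 were higher and 9322 lower. The brightest probes were more often lower than higher under each filter at this scaling. In the brightest of 4 equal classes by mean signal, 13.1% were called higher and 58.9% lower among tested probes, 15.1% and 49.7% without the filter, and 10.4% and 67.6% among probes detected on all arrays. Among the dimmest class the balance turned with the filter, with 44.0% higher and 10.5% lower among tested probes and 22.8% and 46.2% among probes detected on all arrays. Relative to the spike-ins the brightest class turned too, with 53.6%, 52.0% and 50.7% higher and 7.42%, 5.04% and 10.4% lower under the same filters. With the arrays centred on the spike-ins, the median of all tested probes moved from -0.039 to 1.41 log2, and 19962 probes were called higher and 1073 lower (limma). Of the 9722 probes lower relative to the 75th percentile, 1073 were also lower relative to the spike-ins, 6749 were not called and 1900 were called higher. The share of higher probes among all called was thus 47.7% relative to the 75th percentile and 94.9% relative to the spike-ins. It was 32.7% with median centring (median change -0.48), 66.2% with the percentile taken over probes detected on all arrays (median change 0.42), 34.6% with normexp background (median change -0.44), or 26.6% after leaving out spots below their local background, and 48.9% with quantile normalization. The 4 named probes kept their direction on the spike-in scale. There CD417265.1_364 and BU546969.1_505 rose by 9.98 and 7.84 log2, GMFL01-30-B13-R_365 fell by 4.28, and BE823736.1_624 fell by 3.44.

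With slide as a block, limma called 8687 probes higher and 9649 lower at 16 h than in dry seed. Each slide holds 1 dry array, so within a slide dry seed is 1 array assumed to vary like the other stages, and the spread comes from the 1 stage with 2 arrays. That stage is 16 h on slide 1 and 8 h on slide 2. The 8 h arrays of slide 2, replicates 2 and 3, correlated at r = 0.968 across probes, the lowest within any stage. Within slide 1 the counts were 8744 and 8908. Within slide 2, which holds 1 array at 16 h, they were 1 and 1, with 5048 and 4290 at an unadjusted p under 0.05. None of the 4 named probes passed within slide 2, with limma adjusted p values of 0.0757 for 3 of them and 0.0790 for BU546969.1_505.

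After 8 h of imbibition few probes were called against the spread between arrays, and nearly all of the called probes rose. Relative to dry seed, 206 probes were higher and 7 lower (limma, adjusted p under 0.05), out of 3503 at an unadjusted p under 0.05. Of the 3503, 2306 were higher and 1197 lower. Of the 206, 70 were well above background on every array of both stages, with a median change of 4.06-fold and 11 probes at least 8-fold higher. Another 80 were well above background on all 3 arrays at 8 h and on neither dry array, and 20 of these had a bound of at least 8-fold. CD417265.1_364 was already 5.21 ± 0.48 log2 (SE) higher at 8 h, with a limma adjusted p of 0.00606. BU546969.1_505 stood at 3.09 ± 0.58 with a limma adjusted p of 0.0762, and did not pass. GMFL01-30-B13-R_365 (-1.40 ± 0.86) and BE823736.1_624 (-0.91 ± 0.50) did not pass either, with limma adjusted p values of 0.543 and 0.501. A total of 140 probes were well above background on all 3 arrays at 8 h and on neither dry array, against 10 in the opposite direction. The groups did not overlap in 29.1% of tested probes. Arrays in random order would give 20% without the filter, which can favour separation, so the gap between these shares is not read as a result.

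The count of probes called at 8 h was unstable across settings. Leaving out any 1 of the 8 arrays moved the count of higher probes by over 1.5 times. It fell to between 79 and 134 for 7 of the arrays, among them the 3 at 16 h, which enter this comparison only through the shared spread. Only 8 h replicate 3 stood apart, with 710 higher and 81 lower without it. Comparing only the 2 groups, limma called 11 higher and 0 lower (1610 and 794 at an unadjusted p under 0.05), and without the filter on dim probes 78 and 0 (1997 and 1103 at an unadjusted p under 0.05). With normexp background limma called 0 and 0 (625 and 759 at an unadjusted p under 0.05), and 160 and 12 once spots below their local background were left out, a setting chosen after seeing the data. The eBayes step with trend gave 407 and 26, and median centring 313 and 15. Over the probes well above background on all 8 arrays 151 were higher and 24 lower. Among these probes the balance turned at an unadjusted limma p under 0.05, with 1055 higher and 1347 lower. Slide as a block gave 101 higher and 1 lower. Slide 1 alone gave 954 and 342 from 1 dry and 1 array at 8 h, with the spread taken from its 16 h arrays, and slide 2 alone, with 1 dry array, gave 1 and 1 (1222 and 257 at an unadjusted p under 0.05). A common floor for dim values, chosen after seeing the data, gave 29 higher and 30 lower, so that the excess of rises was then gone. With that floor 1204 were higher and 1782 lower at an unadjusted limma p under 0.05. Spike-in scaling left 129 higher and 2 lower.

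Most of the difference between dry seed and 16 h arose after 8 h. Between 8 h and 16 h, 8411 probes rose and 8937 fell (limma, adjusted p under 0.05), with median changes of 1.95-fold and 2.02-fold among the 3893 and 8230 of them that were well above background on every array of both stages. The groups did not overlap in 69.9% of tested probes, where arrays in random order would give 10% without the filter, which can favour separation. CD417265.1_364 rose by a further 3.32 ± 0.43 log2 (SE), with a limma adjusted p of 0.000855, and BU546969.1_505 by 3.30 ± 0.52, with a limma adjusted p of 0.00159. GMFL01-30-B13-R_365 (-4.33 ± 0.77) and BE823736.1_624 (-3.98 ± 0.44) fell, with limma adjusted p values of 0.00259 and 0.000551. A total of 2481 probes were well above background on all 3 arrays at 16 h and on none at 8 h, against 9 in the opposite direction. Relative to the spike-ins, 22152 probes were higher and 692 lower, and the share of higher probes went from 48.5% to 97.0%. With slide as a block limma called 7998 higher and 8695 lower, and within slide 1, which holds 1 array at 8 h, it called 7741 and 7770. Within slide 2, which holds 1 array at 16 h, limma called 0 and 0, with 3691 and 3759 at an unadjusted p under 0.05.

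The transcripts that rose by 8 h mostly went on rising. Of the 206 probes higher at 8 h, 204 were also higher at 16 h than in dry seed, where independent lists would share 63.5. Of the 206, 182 rose again between 8 h and 16 h, and 2 fell. Of the 7 lower probes, 6 were also lower at 16 h, where independent lists would share 2.36. No probe was called in opposite directions at 8 h and 16 h. The 2 comparisons share their dry arrays. In 100 simulations of unchanged groups limma called 0 probes higher in both. Unchanged groups give almost no calls at this threshold, so this count says nothing of how far the shared arrays raise the overlap. The simulations drew all 8 arrays anew with independent noise. They therefore carry the sharing of dry arrays in the design, and no array-wide deviation of the real dry arrays. Over 28785 probes the fold changes at 8 h and 16 h correlated across probes with r = 0.738, against 0.599 in the simulations, and probes are not independent replicates. Their covariance was 0.677 against 0.0643 simulated, a difference of 0.613. The 2 dry arrays cannot be split with replicates on each side, so part of the excess may come from them. With slide as a block limma called 101 probes higher and 1 lower at 8 h, and all of them were called the same way at 16 h. The number called the same way at both times thus went from 210 to 102 because fewer probes were called at 8 h.

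Seed imbibed for 8 h lay closer to dry seed than to 16 h seed. On the line from the mean dry profile to the mean 16 h profile, over 18478 probes well above background on all 8 arrays, the dry arrays lay at 1.55% and 3.35% of the way. The 8 h arrays lay at 21.7%, 34.7% and 10.97% of the way, and the 16 h arrays between 96.1% and 99.6%. Each 8 h array was beyond both dry arrays and short of every 16 h array. Relative to the spike-ins the 8 h arrays lay at 5.58%, 30.0% and -0.41%, so that 1 of them then lay below both dry arrays. The 8 h portions also varied most, with a median SD of 0.21 log2 per probe (n = 3) against 0.16 at 16 h (n = 3). The value in dry seed was 0.097 (n = 2), and a median SD from 2 arrays runs lower than from 3.

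**Figure D3:**
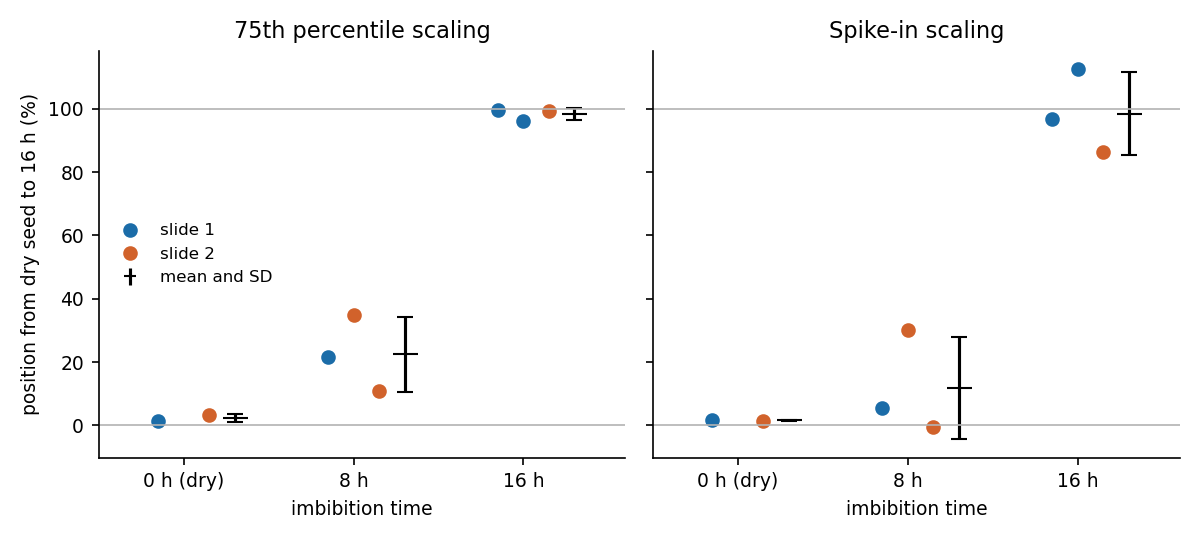
The position of each array on the line from the dry profile (0%) to the 16 h profile (100%) is plotted against imbibition time, for 75th percentile scaling (left) and spike-in scaling (right), with 1 point per array coloured by slide and bars for mean ± SD. On the left the 8 h arrays lie at 10.97%, 21.7% and 34.7%, and on the right at -0.41%, 5.58% and 30.0%.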

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

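The count of other splits of the 6 imbibed arrays was set before its result was seen. The tests of scanner gain, spike-in dose, abundant transcripts, signal floor, swapped arrays, shared dry arrays and choice of scaling were chosen after those values, or values close to them, had been seen.

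The effect against dry seed differed between 8 h and 16 h at 17348 probes by limma's test of 16 h against 8 h. Of the 10 ways to split these 6 arrays, 1, the real one, called that many, and the highest of the other 9 called 0 by limma, with between 122 and 437 probes at an unadjusted p under 0.05. The splits are too few for a share under 0.05. Each other split also mixes arrays of 8 h and 16 h in both groups, which widens the spread, so few calls there were nearly fixed in advance. By the same test the effect against dry seed was higher at 16 h than at 8 h by 3.32 log2 for CD417265.1_364 and by 3.30 for BU546969.1_505. It was lower at 16 h for GMFL01-30-B13-R_365 (-4.33) and for BE823736.1_624 (-3.98).

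Among control features outside the comparisons, 5 were well above background more often than the negative-control spots were, at 10 of 1224 (Fisher's exact test with Bonferroni adjustment over the control features). ETG10_236652 was well above background on 80 of 80 spots and ETG09_48764 on 75 of 80, while (+)eQC-40, ETG05_66023 and ETG08_142674 each were on 5 of 80. Spots of 1 feature on 1 array are not independent replicates. What these features target is not given in the sources used here.

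Soybean signal over the spike-ins was 1.45 log2 higher at 16 h than in dry seed. A higher scanner or hybridisation gain would have raised the spike-ins too, and their mean moved by 0.082, while less spike-in RNA alone would have left the raw soybean signal in place, and its 75th percentile rose by 1.53. Abundant dry-seed transcripts giving way to others with no rise of the total is argued against by the summed soybean signal, 0.41 log2 higher over the spike-ins with every 16 h array above every dry and 8 h array, although this sum rose far less than the percentile, so that such a shift may make up part of it. A lower spike-in dose that happened to coincide with a higher gain stays open, and so do the imbibition time and the selection on water uptake, which the design does not separate. That a given mass of total RNA may hold more messenger RNA at 16 h is 1 hypothesis beside these, and no test here decides between them.

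Replicate 3 at 8 h lay nearest to dry seed of the 8 h arrays, and its negative controls had a median of 7.49 intensity units against 3.16 and 3.73 on the other two. A raised floor would act on dim probes, yet over probes well above background on all 8 arrays it lay at 10.97% of the way to 16 h against 21.7% and 34.7%. A swap with a dry array is left open. The farther dry array lay at 3.35%, below every 8 h array. Yet on the spike-in scale replicate 3 lay at -0.41%, not beyond either dry array. A swap with a sample outside the series and uneven water uptake among portions stay open, and no biological explanation was tested. Without this array limma called 710 probes higher and 81 lower at 8 h than in dry seed.

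Probes that were higher at 16 h than in dry seed had gone further by 8 h than probes that were lower. With 1 dry array used to choose the probes and the other to measure them, the lead was still at least 9.98 percentage points on each of the 3 arrays at 8 h, which argues against the shared dry arrays as its whole source. On the spike-in scale the lead turned, to -39.8 percentage points on 1 array and below 0 on 2 of the 3. Probes were chosen anew there, with 9122 rising and 729 falling against 2130 and 5540 (dry replicate 1 used to choose). The probes called relative to the 75th percentile and detected on all arrays were also placed on the spike-in scale, without separating the dry arrays. Rising and falling ones lay at 10.1% and 13.9%, 34.6% and 21.4%, and 3.51% and 1.94% on 8 h replicates 1, 2 and 3. The choice of scaling, with the probes chosen on it, could therefore account for the order, and no order of rises and falls is drawn from it.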

How the results depend on the processing

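Counts are probes by limma, higher then lower unless stated, and the cause of a change was not tested unless named. The common floor and normexp without spots below background were chosen after seeing the data. For 16 h against dry seed and against 8 h, the counts stayed within 1.5 times under quantile normalization, median centring, slide as a block, slide 1 alone, the replicate number, only the 2 groups compared, eBayes with trend, the deposited values and the common floor. Normexp background gave 0 and 0 at 8 h against dry seed (625 and 759 at an unadjusted p under 0.05), 2115 and 3991 at 16 h against dry seed and 1810 and 5295 at 16 h against 8 h. On 8 h replicate 3 its fitted background was -501 intensity units, set by 2 spots below their local background, and 47.2 without them. Leaving such spots out gave 12 lower at 8 h, 5408 and 14948 at 16 h against dry seed, and 13853 lower at 16 h against 8 h. Spike-in centring gave 129 and 2, then 19962 and 1073, then 22152 and 692. Its own construction shows the cause, a shift of the median of tested probes to 1.41 at 16 h against dry seed and 1.43 against 8 h. The percentile over detected probes gave 4 lower at 8 h and 6247 lower at 16 h against dry seed. Median centring gave 313 and 15 at 8 h, and quantile normalization 12 lower. Without the filter on dim probes the counts were 78 and 0 at 8 h (1997 and 1103 at an unadjusted p under 0.05), 15490 lower at 16 h against dry seed and 14146 lower against 8 h, with 42748 probes tested. Over the 18483 probes above background on all arrays they were 24 lower at 8 h, 4029 higher at 16 h against dry seed and 3912 higher against 8 h, with fewer probes tested. Slide as a block gave 101 and 1 at 8 h, all of them shared with 16 h, so the shared calls went from 210 to 102. Each slide alone has 4 arrays and 1 stage with 2 of them. Slide 1 gave 954 and 342 at 8 h. Slide 2 gave 1 and 1 at 8 h, 1 and 1 at 16 h against dry seed and 0 and 0 at 16 h against 8 h (3691 and 3759 at an unadjusted p under 0.05). Only the 2 groups compared gave 11 and 0 at 8 h (1610 and 794 at an unadjusted p under 0.05), eBayes with trend 407 and 26, and the common floor 29 and 30. A 2-fold minimum left 6115 lower at 16 h against dry seed and 4580 lower against 8 h.

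The replicate number as a block gave 52 and 0 at 8 h (2619 and 1252 at an unadjusted p under 0.05), 8493 and 9357 at 16 h against dry seed and 8186 and 8715 at 16 h against 8 h. Same-numbered arrays of different stages deviated from their group means with correlations between -0.049 and 0.10 (median 0.055), and others between -0.15 and 0.10, so the numbers do not pair the samples, and not every array correlated best with its own number.

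Leaving out each array in turn gave 79 to 710 higher and 1 to 81 lower at 8 h against dry seed. Higher and lower counts were 80 and 8 without dry replicate 1, 103 and 36 without dry replicate 2, 134 and 2 without 8 h replicate 2, 710 and 81 without 8 h replicate 3, and 79 and 1, 128 and 2, and 116 and 2 without 16 h replicates 1, 2 and 3. Without 8 h replicate 1 the higher count lay between those without dry replicate 2 and 16 h replicate 3, with 1 lower. A group left with 1 array is assumed to vary like the others. At 16 h the counts stayed between 7089 and 9323 higher and 7732 and 9973 lower against dry seed, and between 6700 and 8450 higher and 7667 and 8681 lower against 8 h. The 4 named probes kept their direction under all 25 alternatives and passed in 24 of them, the exception being slide 2 alone. They were chosen as the largest called changes without overlap, so a kept direction was nearly fixed in advance. Several settings, among them both filters on dim probes, eBayes with trend and the 2-fold minimum, also leave the fold changes as they are by construction. Tests of gene lists and of 1 probe per gene were not run, as no probe could be named. Signal over background limits the dim probes, of which 9128 were well above background on no array.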

Other observations

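The brightest probes held a smaller share of the summed signal at 16 h than in dry seed. The 100 brightest probes of an array held 37.3 ± 0.074% of its summed soybean signal in dry seed (SD, n = 2), 34.9 ± 1.94% at 8 h (n = 3) and 21.6 ± 1.52% at 16 h (n = 3). The 1000 brightest held 66.4 ± 0.045%, 63.6 ± 2.18% and 49.5 ± 1.00%. Every 16 h array lay below every other array in both shares, with an exact permutation p of 0.2 against dry seed and 0.1 against 8 h, the smallest these group sizes allow, and 0.257 after adjustment over 18 tests. The 1000 probes brightest in dry seed held between 42.4% and 44.0% of the signal on the 16 h arrays. They were chosen on the dry arrays, where they held 66.4%, and such a choice favours a lower share elsewhere. The 1000 brightest at 16 h, of which 645 were shared, held 59.5% and 59.6% on the dry arrays and between 48.5% and 50.3% at 16 h. Relative to the spike-ins, the summed signal of the 1000 brightest in dry seed changed by -0.28 log2 between dry seed and 8 h. It changed by 0.058 between 8 h and 16 h and by -0.22 between dry seed and 16 h. That of all other probes changed by -0.080, 1.25 and 1.17. Brightness also depends on the probe, and several probes can target 1 transcript, so these shares are of probe signal and do not give the number of transcripts.

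Over the steps from 0 h to 8 h and from 8 h to 16 h, limma called 2 probes higher and then lower, and 1 lower and then higher. A further 858 probes rose and 397 fell between 8 h and 16 h without being called in either comparison with dry seed. Of the tested probes, 8931 were called in none of the 3 comparisons. In simulated changes limma recovered 0% of 1.5-fold and 6% of 2-fold changes at 8 h against dry seed, so these counts do not tell how many probes changed and returned.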
